A study of Homo sapiens with 8 samples.

How the data were processed

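The samples were plasmacytoid dendritic cells (pDCs), the blood cells that release large amounts of type I interferon when their endosomal Toll-like receptors are engaged. Per the labels they came from peripheral blood mononuclear cells of 4 people with systemic sclerosis, an autoimmune disease with fibrosis of the skin and internal organs. The cells of each donor were cultured for 6 h in medium alone or with an agent the labels call TLR8L. They do not describe it further. Per the labels' protocols the dose was 200 µg/ml in one field and 100 µg/ml in another, so no dose was used here. RNA was turned into libraries with a low-input NEBNext kit and sequenced in pairs on an Illumina HiSeq instrument.

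The deposited file holds raw counts of read pairs per gene, 1 column for each of the 8 libraries. Per the series design text the authors checked read quality with fastp and used STAR, the human genome build hg38 and Gencode v21 for mapping and counting; the submitters' processing notes name fastp, STAR and edgeR. The versions of those tools and the use of strand in counting are not given in the sources used here. The table lists 58381 Ensembl gene IDs, of which 28067 were at 0 in every library, so no filter on low counts had been applied to it. A current gene symbol was found for 57799 of the IDs and 582 had none. All columns matched a sample, leaving 0 unmatched. Chromosome, start and end are those of GENCODE v44 on hg38, matched by Ensembl ID. IDs that share a place on the same strand, and families of near-identical genes such as the interferon-alpha genes, CCL3 with CCL3L3, CCL4 with CCL4L2 and HSPA1A with HSPA1B, can divide reads between members, so single members of these families are uncertain.

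Groups were taken from the sample titles, which give the donor number and either medium or TLR8L. For 4 of the 8 libraries the treatment characteristic names the other group than the title. The titles were used because each donor then has 1 library of each kind, as the series design text describes. Libraries with the same number come from the same donor. In a check of this pairing, deviations from the group means correlated within each donor at 0.353, 0.827, 0.270 and 0.455 for donors 2, 3, 4 and 6, over genes within a pair of libraries. The medium library of donor 4 correlated better with the TLR8L library of another donor (0.362), and the other 7 libraries best with their own. The pairing was used as a donor block beside a fit without it.

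The total count per library lay between 16417868 and 27145389. A count of 3 corresponded to between 0.111 and 0.183 counts scaled to library size (CPM). Such floors, and all intervals given, cover counting error only, because the reads carry no molecular identifiers.

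Genes with at least 3 CPM in at least 4 of the 8 libraries were tested (7738 genes), a filter at the CPM value the design text states. The main test, fixed before the data were examined, was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) of TLR8L against medium with TMM normalisation, no block, and Benjamini-Hochberg adjustment over all tested genes at 0.05. The design text names edgeR and no block. The same test with the donor as a block was run beside it and is printed wherever it moved a result. Expression values are CPM on TMM-scaled library sizes, as mean ± SD over 4 libraries. Pair directions used log2 of CPM plus 1.

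There were 32 gene lists, also written then, with 605 members in all, of which 604 were found. SOD2 was not, since the symbol tables hold another ID for it. They cover interferons, interferon-stimulated genes, inflammatory cytokines, chemokines, NF-kappaB targets, feedback inhibitors, immediate early genes, the endosomal Toll-like receptor pathway, pDC identity, maturation, MHC class I and class II presentation, the unfolded protein response, glycolysis, oxidative phosphorylation, cholesterol synthesis, apoptosis, metallothioneins, cell cycle and ribosomal proteins. Lists of other cell types held markers of platelets, monocytes, conventional and AXL+ dendritic cells, T cells, B cells, NK cells, red cells, basophils and neutrophils. Lists of RNA quality held mitochondrially encoded, heat shock and nuclear-retained transcripts. The 28 lists with at least 2 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. Library values were compared by exact permutation over all 70 arrangements of 4 against 4 libraries, two-sided, for which the smallest possible p is 0.0286.

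Genes were named by a rule written at the same time. It took the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 10 CPM and the same direction in all 4 pairs. It added up to 4 members of each list and 21 genes of prior interest. Clone names, pseudogenes, sex-linked marker genes and immune receptor segments were left out. By this rule 12 rises and 11 falls qualified. Other members of a list that passed (such as LAMP3, NFKB1 and GZMB) are named with its count, after their values were seen, as are the further genes marked so in the closing text.

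The procedure was tested on data simulated from the real libraries' means, with 200 of 7738 genes changed in each of 3 simulations. Without the block it recovered 0.995% of genes changed 2-fold, 14.9% of those changed 4-fold and 49.5% of those changed 8-fold, and 5.11% of its calls were genes left unchanged. With the block the shares were 10.4%, 61.7% and 80.3%, and 7.60% of calls were unchanged genes. Each fit had its own simulated data, with donor differences only for the fit with the block. The shares therefore do not compare the fits on the same data. No call had the wrong sign. Camera found the 3 raised lists in each fit and none of 60 unchanged lists. The simulated genes varied independently of each other, so this does not show how often lists of co-varying genes pass by chance.

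The alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, 3 other filters, the donor block, other thresholds, leaving out each library and each donor, and grouping by the treatment characteristic. Alternatives chosen after seeing the data were a correction for the GC content of each gene's longest transcript, settings of the blocked test, and counts within 2 lists. The tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Levels of sex-linked marker genes are not reported.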

Results

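The data were gene-level RNA-seq counts of 8 libraries of blood pDCs from 4 donors with systemic sclerosis. Each donor gave 1 library of cells kept in medium for 6 h and 1 of cells cultured with TLR8L for the same time, so each group held 4 libraries. The donors carry the numbers 2, 3, 4 and 6 in the titles. No cells from healthy people were among the samples. Total counts were 17449732, 16417868, 16798917 and 24701204 in the medium libraries of donors 2, 3, 4 and 6, and 27107926, 27145389, 24462857 and 20247818 in their TLR8L libraries.

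TLR8L against medium was the comparison the design set out. It addressed how the transcriptome of these samples of patients' pDCs responds to this agent within 6 h. Monocyte markers were present too, with a median between 3.95 and 8.35 in log2 of CPM plus 1 in the medium libraries. The changes below, those of cytokine and chemokine genes included, therefore cannot be assigned to pDCs alone. Rises were ranked among genes that passed without the donor block and met the naming rule. The 12 largest were 6 type I interferon genes, the activation marker CD69, the cytokine genes IL23A and TNF, CCND2, SOCS3 and BCL2A1. CCND2 encodes a cyclin, SOCS3 a signalling inhibitor and BCL2A1 a survival protein. IL6, with a log2 change of 6.77, and CCL4, with 5.15, passed only with the block and so were not ranked. CCND2 went from 18.8 ± 8.51 to 577 ± 428 CPM (log2 change 4.94). IFNB1, which encodes interferon-beta, averaged 0.628 ± 0.274 CPM in medium and 182 ± 220 CPM with TLR8L (SD, n = 4), a log2 change of 8.17. The cytokine gene TNF rose from 6.13 ± 3.75 to 167 ± 58.4 CPM, BCL2A1 from 65.3 ± 24.7 to 1700 ± 779 CPM, and CD83, a marker of dendritic cell maturation, from 88.3 ± 37.4 to 1379 ± 362 CPM. Among the genes that fell, RUNX2, a transcription factor of the pDC lineage, went from 100.4 ± 22.0 to 10.3 ± 4.41 CPM.

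Of the 7738 genes tested, 52 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38 of them higher and 14 lower with TLR8L. With the donor as a block 611 changed, 360 higher and 251 lower, and these included all 52 in the same direction. Upper-quartile scaling turned the blocked split to 299 higher and 350 lower. Without the block, no gene passed edgeR's test once the medium library of donor 2 or that of donor 6 was left out, with 817 and 787 genes at an unadjusted p under 0.05, nor without both libraries of either donor, with 543 and 889 such genes. Over all libraries DESeq2 called 502 genes and limma-voom 35. Without the medium library of donor 4 the count was 142, without the TLR8L library of donor 2, 4 or 6 it was 26, 19 or 21, and without both libraries of donor 3 it was 34. Blocked counts were 117, 173 and 311 without donors 2, 3 and 6.

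**Figure D1:**
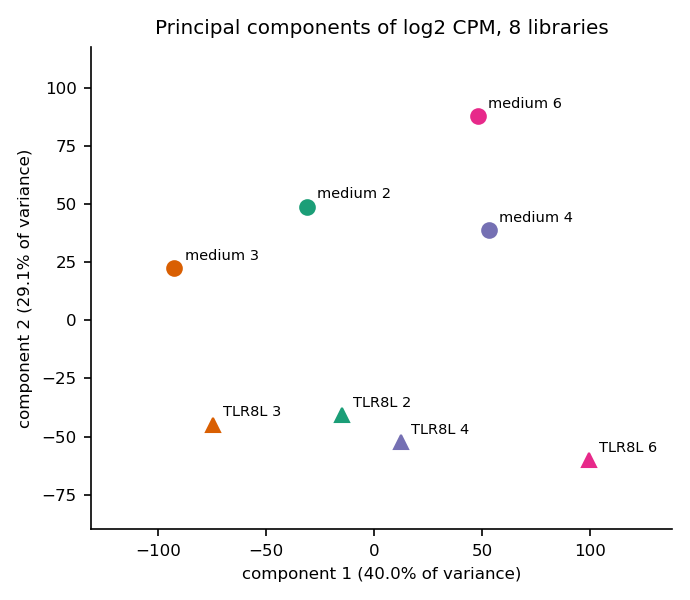
Principal components of log2 CPM over the 7738 tested genes for the 8 libraries, with the share of variance on each axis; circles are medium and triangles TLR8L, and colours mark donors. The groups separate along the second component, where medium libraries lie between 22.5 and 88.0 and TLR8L libraries between -60.2 and -40.7.

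Of the interferon genes 6 of 7 rose without the block, and of the genes known to respond to interferon 19 of 43 did with it. IFNA2 (ENSG00000188379.6, chromosome 9, 21384255 to 21385398) averaged 4.18 ± 1.82 CPM in medium and 1902 ± 2326 CPM with TLR8L (SD, n = 4). It was higher in all 4 donors, at 331.5, 146.8, 5169 and 1960 CPM in the TLR8L libraries of donors 2, 3, 4 and 6. Of the 7 interferon genes tested, IFNA1, IFNA2, IFNA5, IFNA8, IFNB1 and IFNW1 rose, 7 did when adjusted over the list alone, and 7 did with the block. With no filter beyond a total count above 0, which tests more of the list, 17 interferon genes rose without the block. Besides the library losses that ended all calls, the unblocked count was 1 without the TLR8L library of donor 6, 4 without that of donor 4 or the medium library of donor 3, and 3 without donor 4. The blocked count was 7 without any 1 donor. The log2 changes were 9.04 for IFNA8, 8.83 for IFNA2 and 8.29 for IFNW1, with adjusted p of 0.0279, 0.0225 and 0.0225 by edgeR. In the medium libraries IFNA2 had 83, 45, 79 and 125 counts, which was between 0.0306% and 0.0851% of its counts in the other libraries. In 3 of the 4 this was the lowest share of any abundant gene compared, and whether these counts come from the cells in medium was left open, so the folds are uncertain. limma-voom, with 35 calls in all, called none of the 7, all of which had an unadjusted p under 0.05 in edgeR, and DESeq2 called 7. The type III gene IFNL1 was under the filter, at 0.0344 ± 0.0438 CPM in medium and 4.06 ± 6.87 CPM with TLR8L. By camera the list stood above other genes (adjusted p = 2.48e-12, or 0.0995 with an estimated correlation). IFNA1, IFNA5, IFNA8, IFNB1 and IFNW1 were under 3 CPM in each medium library. The filter could therefore admit them only if they were high in all 4 TLR8L libraries. Their direction in the tests was thus set by the filter, and the list result is not separate support.

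Interferon-stimulated genes had log2 changes above 0 in 43 of 43 tested members, with a median of 2.05. None passed edgeR's test without the block (0 when adjusted over the list alone), while 13 had an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 0. With the block 19 rose, or 42 when adjusted over the list alone, and the median was 4.21. Examples were TRIM22, an antiviral protein gene, with a blocked log2 change of 2.42 (adjusted p = 0.0180), and IFI35, with 3.40 (adjusted p = 0.0256). CXCL10, a chemokine induced by interferon, averaged 521 ± 995 CPM in medium and 7061 ± 3505 CPM with TLR8L, and rose only in the blocked test, by a log2 of 7.29 (adjusted p = 0.0372 against 0.336 without the block, edgeR). The medium library of donor 4 stood apart in this group. Its median level over the list was 8.73 in log2 of CPM plus 1, against 3.38, 4.03 and 3.49 in the other medium libraries and between 8.14 and 9.02 with TLR8L, while its interferon genes were at the medium level. Without that library 31 interferon-stimulated genes rose in the unblocked test. In donor 4, 13 of the 43 members were higher in the medium than in the TLR8L library, where the median level was 8.81. With the block, 42 rose without donor 4, but 1, 1 and 5 without donors 2, 3 and 6. Camera placed the list above other genes (adjusted p = 5.66e-23, or 0.180 with an estimated correlation). Fry gave an adjusted p of 0.0463 without the block and 0.0612 with it.

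**Figure D2:**
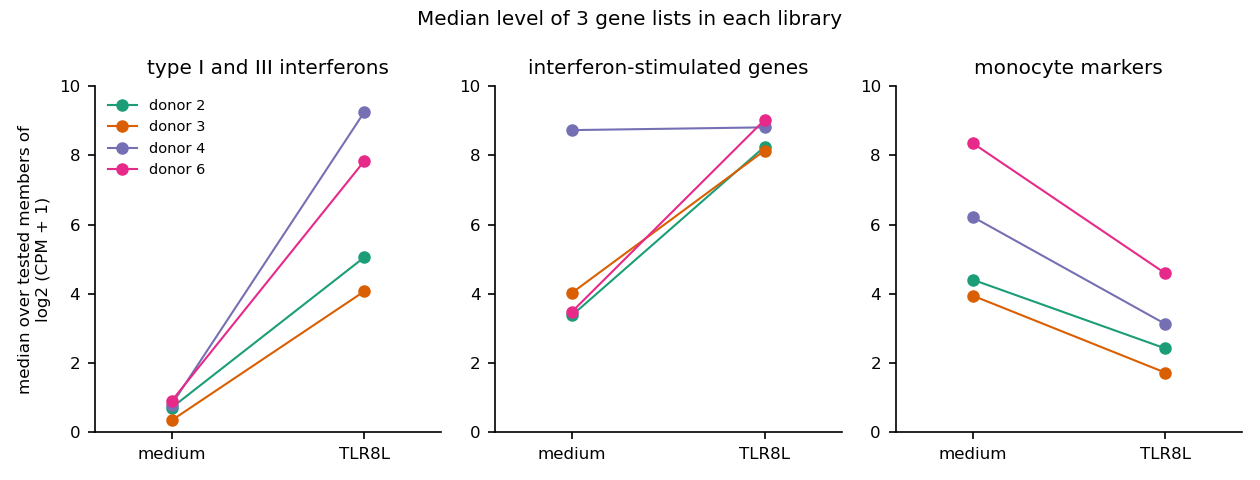
Median over the tested members of 3 gene lists, as log2 of CPM plus 1, in each library, with a line joining the medium and TLR8L libraries of 1 donor. The medium library of donor 4 lies at 8.73 for the interferon-stimulated genes and at 0.806 for the interferon genes, and all 4 lines of the monocyte markers go down.

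Some inflammatory mediators rose as well. Among 11 tested cytokine genes, TNF (ENSG00000232810.3, chromosome 6, 31575565 to 31578336) and IL23A, which encodes a subunit of interleukin 23, passed the test, with log2 changes of 4.76 and 5.24 and an adjusted p of 0.00958 each by edgeR, and higher values in all 4 donors. Adjusted over the list alone 6 rose, and with the block 6 did, among them IL6, at 1.25 ± 1.98 CPM in medium and 132 ± 152 CPM with TLR8L (blocked log2 change 6.81, adjusted p = 0.00848 by edgeR against 0.0963 without the block). None of 18 chemokine genes passed without the block, although 9 had an unadjusted p under 0.05, 4 passed when adjusted over the list alone, DESeq2 called 8 and limma-voom 0. With no filter beyond a total count above 0, 7 cytokine and 8 chemokine genes rose in edgeR without the block. With the block 9 chemokine genes rose, or 12 when adjusted over the list alone, and 3 and 4 rose without donors 2 and 3. Without the block 4 cytokine and 2 chemokine genes rose once the medium library of donor 4 was left out, 3 cytokine genes without the TLR8L library of donor 3, and 2 chemokine genes without donor 4. CCL4, a chemokine that attracts T cells and monocytes, went from 199 ± 218 to 7039 ± 5067 CPM (blocked log2 change 5.72, adjusted p = 0.00158), CCL3 from 14.2 ± 13.9 to 438 ± 340 CPM (5.14, adjusted p = 0.00105) and CXCL8, a chemokine for neutrophils, from 606 ± 872 to 1169 ± 861 CPM (1.70, adjusted p = 0.0428, edgeR). Camera gave an adjusted p of 2.00e-08 for the cytokines, which held without the block when the correlation was estimated (adjusted p = 0.0450) and did not with the block (adjusted p = 0.162), and 9.09e-08 for the chemokines (adjusted p = 0.0995 with an estimated correlation).

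NF-kappaB targets and regulators, the transcripts of the main inflammatory pathway below Toll-like receptors, had log2 changes above 0 in 17 of 17 tested members. BCL2A1, REL and NFKB1 rose, 9 members did when adjusted over the list alone, and 8 with the block (12 over the list alone; 5 without donor 3). Without the block 1 rose without the TLR8L library of donor 4 or without donor 4, and 2 without donor 3. REL, a subunit of NF-kappaB, went from 39.2 ± 7.16 to 231 ± 99.8 CPM, a log2 change of 2.56 (adjusted p = 0.0225 by edgeR). Of 10 tested feedback inhibitors, SOCS3, an inhibitor of cytokine signalling, and ATF3, a stress-induced repressor, rose by 4.72 and 3.68 on the log2 scale, and IRAK3, an inhibitor of Toll-like receptor signalling, fell from 19.4 ± 22.5 to 0.159 ± 0.125 CPM (adjusted p = 0.0355, edgeR). The IRAK3 levels in medium were 8.0, 2.66, 14.5 and 52.4 CPM in donors 2, 3, 4 and 6. Their order across donors was that of the monocyte marker median, which was also lower with TLR8L in each donor. CCL3, CCL4 and IFNA2, higher with TLR8L in all 4 donors, also had this order in medium. The order is therefore not particular to monocyte markers. Over the list alone 4 rose and 1 fell, and with the block 4 rose and 1 fell. limma-voom without the block called none of the 3, DESeq2 4 higher and 1 lower, and edgeR 1 higher and 1 lower after GC correction. In edgeR all 3 unblocked calls also ended without the TLR8L library of donor 2 or without donor 4, both rises ended without donor 3, 1 member rose without the TLR8L library of donor 4 or 6, and the fall ended without the TLR8L library of donor 3, 4 or 6. With the block 2 members rose without donor 2 or 3, and the fall ended without donor 2, 4 or 6.

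The immediate early gene NR4A3 rose from 9.98 ± 5.79 to 156 ± 86.3 CPM, 1 of 6 tested members of its list, also with the block and over the list alone. This call ended without the TLR8L library of donor 2, 4 or 6 or without donor 4, and the blocked count was 1 without each donor. With each of 3 other filters 1 member of the list also fell in both tests. Camera gave adjusted p values of 2.82e-12 for the NF-kappaB list (adjusted p = 0.0535 with an estimated correlation) and 0.00794 for the feedback inhibitors. For the feedback inhibitors it was 0.366 with an estimated correlation and 0.0531 after GC correction. It was 0.0840 without the medium library of donor 3 and 0.0706 without the TLR8L library of donor 6. Fry gave the feedback inhibitors an adjusted p of 0.131 without the block and 0.00461 with it. The immediate early genes had a camera adjusted p of 0.0899. It lay between 0.0136 and 0.0382 without the medium library of donor 4 or 6, the TLR8L library of donor 2, or donor 4.

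Maturation and co-stimulation genes, which equip dendritic cells to activate T cells, rose in part. CD69, an early activation marker, went from 48.7 ± 56.6 to 2365 ± 1104 CPM (log2 change 5.60, adjusted p = 0.0275 by edgeR), and CD83 (chromosome 6, 14117256 to 14136918) rose by 3.96 (adjusted p = 0.00958). LAMP3, a lysosomal protein of mature dendritic cells, was the other of 3 calls among 14 tested members, 7 passed when adjusted over the list alone, and 8 with the block in both adjustments. The unblocked count was 1 without the TLR8L library of donor 2, 4 or 6 and 2 without that of donor 3, and the blocked count 5 without donor 3. CD40 rose by 3.69, CCR7, the receptor that guides cells to lymph nodes, by 3.27 and CD80 by 3.38 in the blocked test, with adjusted p of 0.00428, 0.00139 and 0.0431 against 0.0915, 0.254 and 0.302 without the block (edgeR). CD86 averaged 40.1 ± 26.5 and 55.2 ± 32.6 CPM and passed in neither test. Camera gave an adjusted p of 4.53e-09, with 0.0450 under an estimated correlation and 0.0905 under an estimated correlation with the block.

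**Figure D3:**
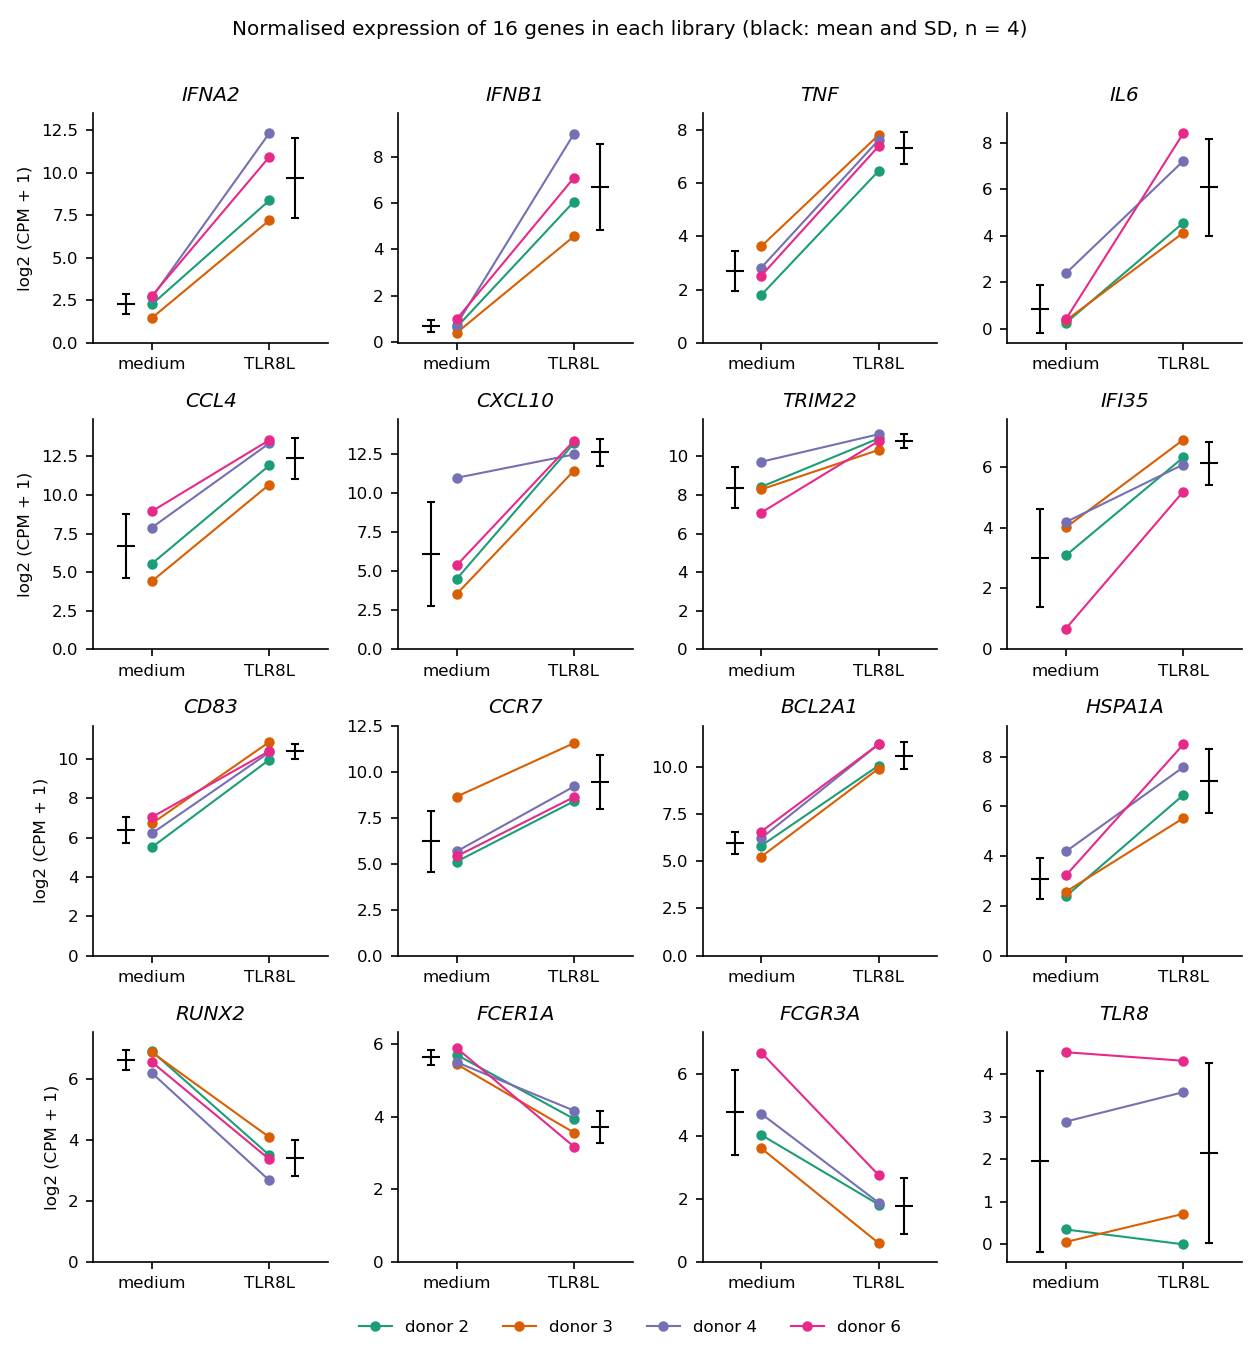
Log2 of CPM plus 1 for 16 genes in each library; each coloured line joins the medium and TLR8L libraries of 1 donor, and black marks give the mean and SD of 4 libraries. IFNB1, TNF and CD83 were higher with TLR8L in all 4 donors, RUNX2 and FCER1A lower in all 4, and TLR8 higher in 2.

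A few antigen presentation genes passed in edgeR, with the donor block alone. For MHC class I, 5 of 19 tested members rose with the block (11 over the list alone), among them HLA-F by a log2 of 1.81 (adjusted p = 0.0257, edgeR). For MHC class II, HLA-DQA1 rose by 1.74 (adjusted p = 0.0163), 1 of 12 members, or 10 over the list alone. The class I rises all ended without donor 2, without donor 3 and without donor 6, and 1 member fell without donor 6. The class II rise ended without donor 2 or 3, and 2 rose without donor 4. With the block 5 class II members rose after GC correction, and 2 with RLE factors or with a minimum of 3 CPM in 1 library. Without the block none passed in either list, with 4 unadjusted p values under 0.05 in each, 3 class I members over the list alone, 3 DESeq2 calls in each and 0 limma-voom calls in each. Camera gave adjusted p values of 0.000111 and 0.000233 (adjusted p = 0.126 and 0.262 with an estimated correlation), and the class II call ended in fry (0.0526).

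The genes that define pDCs went both ways. RUNX2 (ENSG00000124813.21, chromosome 6, 45328157 to 45664349) fell by 3.28 on the log2 scale (adjusted p = 0.0117 by edgeR, lower in 4 of 4 donors), the 1 call among 24 tested members, with 2 when adjusted over the list alone. With the block GZMB, which encodes granzyme B, rose by 1.67 and RUNX2, LAMP5, SERPINF1 and SCN9A fell. The blocked rise ended without donor 2, 3 or 6, and 1 and 2 members fell without donors 2 and 3. CLEC4C, the surface marker also called BDCA-2, averaged 465 ± 358 CPM in medium and 515 ± 205 CPM with TLR8L and passed in neither test. The list as a whole did not pass (camera adjusted p = 0.280; 0.0124 without the medium library of donor 6), and its median log2 change was -0.20 without the block and 0.07 with it. IL3RA, the gene for CD123, is listed at 0 in every library, as nearly all genes of the pseudoautosomal regions are: their 45 X copies hold 1 read pair in total. This value therefore says nothing about its expression.

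The receptor genes TLR7 and TLR8 did not pass in edgeR with or without the block. TLR8 was low, at 7.14 ± 10.2 CPM in medium and 7.62 ± 9.03 CPM with TLR8L, and the libraries of donors 2 and 3 had at most 0.644 CPM. Its log2 change of 0.09 turned to -0.29 in limma-voom. In medium TLR8 had 0.274, 0.039, 6.39 and 21.9 CPM in donors 2, 3, 4 and 6. This was the order across donors of the monocyte marker median, but also that of CCL3 and CCL4, which were higher with TLR8L in each donor. TLR8 was lower with TLR8L in 2 donors only. TLR7 averaged 550 ± 620 and 852 ± 348 CPM (log2 change 0.63, adjusted p = 0.779 by edgeR), with 1480 CPM in the medium library of donor 4. TLR9 is listed at 0 in every library and shares its place and strand with another gene ID, so its expression cannot be read from the table. In the endosomal Toll-like receptor pathway 0 of 18 tested members passed in edgeR with or without the block, 2 had an unadjusted p under 0.05 without it, and DESeq2 called 1 and limma-voom 0. With the block DESeq2 called 3 higher and 1 lower and limma-voom 2 higher and 1 lower. With no filter beyond a total count above 0 edgeR called 1 member without the block, and 3 higher and 1 lower with it, and 2 rose with the block without donor 4. TASL, an adaptor of that pathway, averaged 463 ± 315 and 1816 ± 1305 CPM, and the interferon regulator IRF7 13.5 ± 8.83 and 37.4 ± 9.58 CPM. Camera gave an adjusted p of 0.189, and 0.0254 with no filter. Fry gave an adjusted p of 0.129 without the block and 0.0208 with it.

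A few stress and apoptosis genes rose without the block. The heat shock genes HSPA1A and HSPA1B rose by 4.30 and 4.64 on the log2 scale (adjusted p = 0.0422 and 0.0225, edgeR), 2 of 7 tested members, with 4 over the list alone, 6 with the block and 7 over the list alone with the block. limma-voom called neither without the block and DESeq2 4 of the list, and in edgeR both calls ended after GC correction, without the TLR8L library of donor 4 and without donor 3 or 4. The count was 1 with either of 2 other filters, without the medium library of donor 3 and without the TLR8L library of donor 2 or 6. The blocked heat shock count was 2 without donor 2 or 3. PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 41.9 ± 8.66 to 240 ± 49.6 CPM (adjusted p = 0.00958), the 1 call among 13 apoptosis genes, with 6 over the list alone, 6 with the block (2 without donor 2) and 10 with both. Without the medium library of donor 3, 2 apoptosis genes rose in the unblocked test. Over all libraries without the block, DESeq2 called 5 apoptosis genes higher and edgeR with no filter 4. Of the unfolded protein response, 4 of 18 members rose with the block (5 over the list alone) and none without it (4 unadjusted, 1 over the list alone, DESeq2 2, limma-voom 1); SEC61B, a subunit of the channel into the endoplasmic reticulum, had a blocked log2 change of 1.67 (adjusted p = 0.0140 against 0.0634 without the block). The blocked rises of this list ended without donor 2, and 2 members rose without donor 3 or 6, with upper-quartile factors or with filterByExpr. Without the block 1 member rose with no filter or after GC correction.

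Camera gave adjusted p values of 8.87e-07 for heat shock, 1.55e-07 for apoptosis and 0.00334 for the unfolded protein response, and with an estimated correlation the adjusted p values were 0.0748, 0.0535 and 0.264. The last call also ended in fry (0.0553).

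Few members of the metabolic and growth lists passed. With the block 5 of 14 cholesterol synthesis genes rose (9 over the list alone) in edgeR, and 2 of 24 oxidative phosphorylation genes, CYCS by a log2 of 1.11 and COX5A by 1.42 (2 over the list alone). All of these calls ended without donor 2 or without donor 3, 2 cholesterol synthesis genes rose without donor 4 or 6 and 3 with upper-quartile factors, and 1 oxidative phosphorylation gene without donor 6. PCNA, a DNA replication factor, fell by 1.15 on the log2 scale with the block (adjusted p = 0.0461), the 1 call among 9 cell cycle genes. It ended without each of the 4 donors, with filterByExpr, with a minimum of 3 CPM in 1 library and after GC correction. Without the block these lists had no call, with 3, 2 and 2 unadjusted p values under 0.05, and DESeq2 called 0, 2 and 0 and limma-voom none. No member of the 12 glycolysis or 78 ribosomal protein genes passed in edgeR with or without the block, with 0 and 1 unadjusted, and none in DESeq2 or limma-voom without the block. With it DESeq2 called 1 glycolysis gene higher and 5 ribosomal protein genes higher and 1 lower, and limma-voom 1, 3 and 1. In blocked edgeR with no filter 1 glycolysis gene rose and 1 ribosomal protein gene fell, and 1 ribosomal protein gene fell with upper-quartile factors and 1 rose after GC correction.

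For these lists camera gave adjusted p values of 0.00141 for cholesterol synthesis, 0.0110 for oxidative phosphorylation and 0.00925 for ribosomal proteins, whose median log2 change was 0.20 (with an estimated correlation the adjusted p values were 0.0995, 0.240 and 0.509); the ribosomal call ended without the medium library of donor 3 (0.105), without donor 4 (0.0976), after GC correction (0.0545) and in fry (0.145). The adjusted p was 0.505 for glycolysis and 0.805 for the cell cycle. Metallothioneins had no tested member, with at most 2.18 CPM on average.

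Markers of other cells were measured beside these groups. In the blocked test 5 of 8 monocyte markers fell with TLR8L. Over the list alone 7 fell and MNDA rose, by a blocked log2 of 3.52, and 1 marker also rose with the block in DESeq2, in limma-voom, with no filter, after GC correction and without donor 4. Without the block none passed in edgeR, with 5 unadjusted p values under 0.05, 5 over the list alone, 5 in DESeq2 and 0 in limma-voom. With no filter beyond a total count above 0, 7 fell in edgeR without the block. The 5 of the blocked test included FCGR3A, from 38.2 ± 42.0 to 2.89 ± 2.18 CPM (adjusted p = 0.00727 against 0.127 without the block, edgeR), and CLEC7A, from 202 ± 302 to 9.34 ± 7.58 CPM (adjusted p = 0.0265 against 0.169). The median level of the list was highest in the medium library of donor 6, at 8.35 in log2 of CPM plus 1 against 4.41, 3.95 and 6.22 in the other medium libraries. FCER1A, a marker of conventional dendritic cells that pDCs also express, fell from 49.5 ± 7.24 to 12.6 ± 3.95 CPM (adjusted p = 0.0434), 1 of 5 tested members of its list and 2 with the block. This unblocked call ended with each of 3 other filters and without any library or donor except the medium library of donor 4. The blocked calls ended without donor 2, and 1 member fell without donor 3. Camera placed both lists below other genes, with adjusted p values of 0.00255 for monocytes and 0.00759 for the other dendritic cells. With an estimated correlation they were 0.264 and 0.103, and the monocyte call ended in fry without the block (0.0933). With the block the monocyte list had an adjusted p of 0.00461 in fry and 0.212 in camera with an estimated correlation.

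Platelet, T cell and B cell lists had 2 tested members each and the NK cell list 5, and none of these passed in edgeR with or without the block, nor in DESeq2 or limma-voom without it, where none had an unadjusted p under 0.05. With the block DESeq2 called 1 B cell marker lower and limma-voom none, and in edgeR the B cell marker BANK1, lower in 4 of 4 donors, passed when adjusted over the list alone. In the blocked edgeR test 1 B cell marker fell without donor 6 and 1 with no filter. Their camera adjusted p values were 0.898, 0.881, 0.840 and 0.293, the last 0.0480 without the medium library of donor 6. The means reached 106 ± 112 CPM for GNLY of NK cells and 132 ± 78.0 CPM for IL7R of T cells, both with TLR8L, and PF4 of platelets stayed under 1 CPM on average. Red cell and basophil markers had no tested member and neutrophil markers 1.

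**Figure D4:**
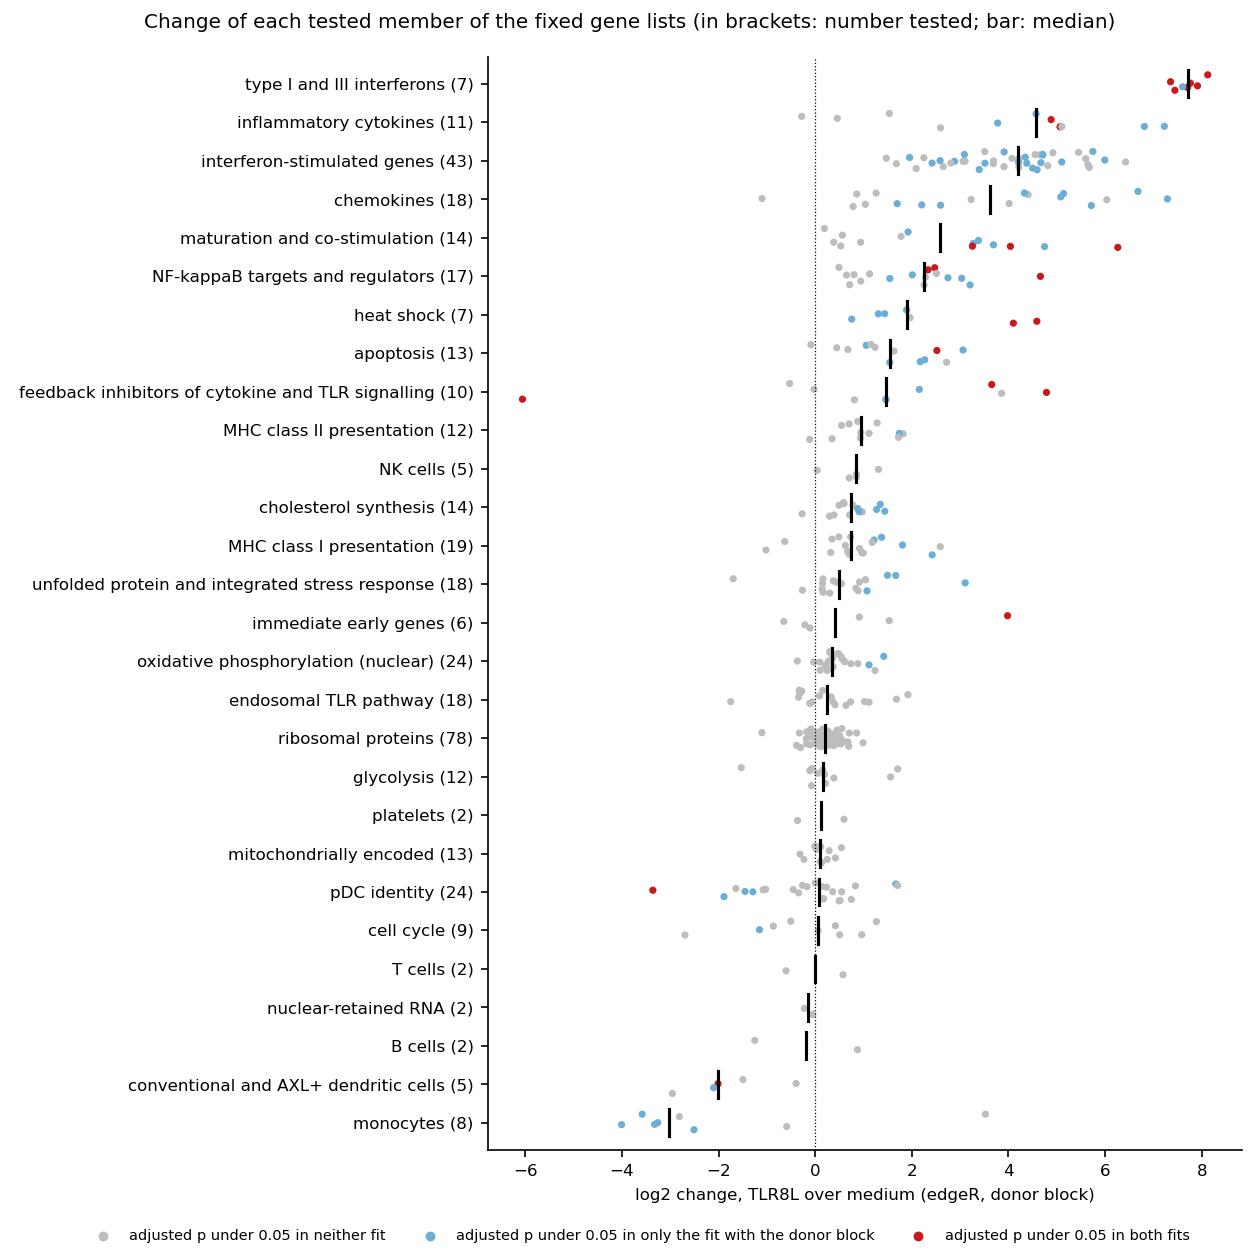
Log2 change with TLR8L in edgeR's test with the donor block for every tested member of the 28 lists, 1 point per gene, ordered by the list median (black bar). Interferons have a median of 7.71 and monocyte markers one of -3.04, and colours show which members passed in both tests, only with the block, or in neither.

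Library values were compared by an exact permutation test that does not use the pairing. The mean total count was 18841900 ± 3929350 in medium and 24741000 ± 3248050 with TLR8L (exact p = 0.0857, adjusted 0.429), and the 50 most abundant genes held 28.7 ± 4.18% and 34.7 ± 4.98% of counts (exact p = 0.143). Mitochondrially encoded genes held 1.66 ± 0.568% and 1.39 ± 0.682% (exact p = 0.6), and 18500 ± 2178 and 17173 ± 1827 genes had at least 1 count (exact p = 0.429). Within donors, the number of genes detected and the TMM factor were lower with TLR8L in 4 of 4, the share of the 50 most abundant genes and the GC trend higher in 4 of 4, the total count higher in 3 and the mitochondrial share higher in 1. Mitochondrially encoded genes as a list had a camera adjusted p of 0.575 (0.0168 without the TLR8L library of donor 3), and the nuclear-retained transcripts MALAT1 and NEAT1 one of 0.805. The heat shock list, also one of RNA quality, stood above other genes (camera adjusted p = 8.87e-07, or 0.0748 with an estimated correlation). The log2 abundance of genes relative to the mean of all libraries correlated with GC content across genes at a Spearman rho of 0.323 and 0.348 in the medium and TLR8L libraries of donor 3 and at -0.317 and -0.239 in the medium libraries of donors 4 and 6, and genes are not independent replicates. With a correction for these trends, chosen after seeing them, 75 genes changed without the block and 713 with it, while the number of lists past the threshold was 15 against 17.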

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

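The tests of the first 3 patterns below were chosen after those results were seen, and the tests on other splits of the samples before. In groups of 4 libraries, a library was singled out when its gap to the nearest other as a share of the group's range (given below) exceeded Dixon's 95% critical value. This held in 13 of 170 groups, and chance flags about 1 in 20 groups.

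In medium, IFNA1 was lowest (0.8648) and RPS29 lowest (0.9597) in the library of donor 3, where CCR7 was highest (0.843). TLR7 (0.9584) and IL6 (0.9241) were highest in the medium library of donor 4, and ZFP36L2 (0.9151) and the total count (0.8754) in that of donor 6. With TLR8L, RPS27L was highest in the library of donor 2 (0.8717) and MS4A1 in that of donor 4 (0.8476). In the TLR8L library of donor 6, SOCS3 (0.8327), MT-ATP8 (0.8572) and PF4 (0.878) were highest and TRAF3IP3 lowest (0.844). IFNA1 had at most 3 counts in each medium library, so its value there reflects counting error.

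Interferon-stimulated genes were high in the medium library of donor 4, with 42 of 43 above the mean of the other medium libraries. Carry-over from the TLR8L library of that donor would bring interferon transcripts too, but a median of 0.0308% of their TLR8L excess was present, against 69.5% for the interferon-stimulated genes. An exchange of that donor's 2 libraries is argued against by 7 of 7 interferon genes being higher in the library titled TLR8L. After GC correction the median log2 excess was 5.137 (SD 1.83 over genes), against 4.83 (SD 1.92) before, so the library's GC trend is not the whole cause. Exposure of these cells to interferon before or during culture may explain the pattern, which stays a hypothesis because no sample tests it, while cells of this donor taken before culture would.

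Of 8 monocyte markers 5 fell with TLR8L in the donor-blocked test. Fewer monocytes would lower alike only markers that other cells do not express and that TLR8L does not change. MNDA (blocked log2 change 3.52) and MS4A6A (-0.59) lay at least 7.754 of their own standard errors above the median of the other 6 markers (-3.29). Whether MNDA and MS4A6A are such markers was not tested, so their gap does not argue against fewer monocytes. For those 6 a common fall had a chi-square p of 0.00658, which became 0.217 without VCAN and 0.298 without LYZ, so fewer monocytes and a lower expression per cell cannot be told apart for them. After GC correction the median over 8 markers was -3.13, against -3.04 before, which argues against the GC trends.

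Interferon transcripts in the medium libraries were few. Reads assigned to the wrong library would put a floor under the share of every abundant gene, and in 0 medium libraries did the interval of the IFNA2 share lie above the lowest share of the other abundant genes. This allows misassigned reads but does not decide for them. IFNA2 was among the largest rises, so its share in medium was likely to be low whatever its source. Expression by cells in medium stays open, since the smallest adjusted chi-square p for the interferon genes as a mixture of the TLR8L libraries was 0.13.

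Among the 35 splits of the 8 libraries, 1, the real one, gave 52 or more changed genes, and the highest other gave 0. These splits set the pairing by donor aside, so they cannot exclude chance for paired libraries. Of the 8 splits that part all 4 pairs, 1 gave as many as the 52 genes, and 1 as many as the 611 genes changed with the donor block, and the highest other gave 0 for both, but 8 splits are too few for a share under 0.05. The real split gave 17 lists past the threshold, 1 of 35 splits gave as many, and the highest other, which exchanges the 2 libraries of donor 2, gave 16. That split keeps the real contrast in 3 of 4 donors, and splits that exchange 2 of the 4 donors' pairs gave 1 list each. Other splits with 2 medium and 2 TLR8L libraries on each side gave between 3 and 8 lists. Several lists thus also passed where the sides did not differ in their number of TLR8L libraries.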

How the results depend on the processing

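The GC correction, the settings of the donor-blocked test and the counts within the interferon-stimulated and monocyte lists were chosen after results were seen. The cause of each difference was not tested.

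DESeq2 gave 502 changed genes (260 higher, 242 lower), limma-voom 8 lower genes, and no filter beyond a total count above 0 gave 359 (225 higher, 134 lower). filterByExpr and a minimum of 3 CPM in 1 library each gave 9 lower genes. At an adjusted p under 0.01, 8 genes changed, 8 higher and 0 lower. Grouping by the treatment characteristic gave 0 changed genes (0 higher, 0 lower; 1917 at an unadjusted p under 0.05 in edgeR, against 1067 with the titles; DESeq2 and limma-voom were not run on it).

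The donor block gave 611 changed genes, 360 higher and 251 lower, and 19 interferon-stimulated genes higher. With the block, DESeq2 gave 1776 (916 higher, 860 lower), limma-voom 1146 (610 higher, 536 lower) and no filter 1497 (843 higher, 654 lower). Interferon-stimulated genes higher with the block were 42 in DESeq2, 30 in limma-voom and 43 with no filter, and monocyte markers lower were 9 with no filter. Without the block the interferon-stimulated genes higher were 9 in DESeq2 and 15 with no filter. Camera with an estimated correlation passed 2 lists and fry 12, against 17.

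Leaving out libraries or donors gave between 0 and 142 changed genes (0 to 124 higher, 0 to 18 lower), and with the donor block between 117 and 519 (73 to 378 higher, 44 to 144 lower). The interferon-stimulated genes higher ranged from 0 to 31, and with the block from 1 to 42; the monocyte markers lower ranged from 4 to 5 and the lists passing from 15 to 20.

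Directions turned for lists that did not pass in camera. These were platelets (adjusted p 0.973 with the donor block, 0.388 with filterByExpr, 0.45 with 3 CPM in 1 library), T cells (0.999 with filterByExpr) and B cells (0.421 with no filter). When libraries or donors were left out, adjusted p ranged from 0.0124 to 0.916 for pDC identity, 0.0822 to 0.957 for glycolysis, 0.458 to 0.98 for the cell cycle, 0.42 to 0.99 for platelets, 0.552 to 0.98 for T cells, 0.353 to 0.982 for B cells, 0.0168 to 0.976 for mitochondrially encoded and 0.479 to 0.988 for nuclear-retained RNA.

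Log2 changes of genes that did not pass also turned: GNG11 to 0.01531 and NEAT1 to 0.01134 with GC correction, TLR8 to -0.2924 in limma-voom, and CD3G to -0.0819 with upper-quartile factors, -0.9397 in limma-voom and -0.6025 with the donor block. Leaving out libraries or donors gave -0.7502 to 1.013 for CAVIN2, -0.6935 to 0.6428 for GNG11, -1.736 to 0.5568 for CD3G, -1.423 to 2.167 for MS4A1, -0.1542 to 2.157 for KLRB1, -0.1781 to 1.507 for GNLY, -0.2498 to 0.1607 for NEAT1, -0.8928 to 1.778 for TLR8, -0.1993 to 0.7381 for CLEC4C and -0.001134 to 0.83 for CD86.

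Over all settings, 530 list values kept their direction and side of the threshold, 26 were weaker, 8 stronger and 24 turned. For named genes 1261 kept both, 260 were weaker, 62 stronger and 34 turned.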

Other observations

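The genes in this part were chosen after their values were seen, except DACH1 and ZFP36L2, which the naming rule picked. RGS1 and RGS16, regulators of G protein signalling, rose with TLR8L from 40.0 ± 15.6 to 758 ± 299 CPM and from 5.14 ± 1.69 to 79.2 ± 12.4 CPM (SD, n = 4), with an adjusted p of 0.00958 each by edgeR. CALCRL, a receptor for calcitonin gene-related peptide and adrenomedullin, rose from 55.0 ± 26.5 to 737 ± 108 CPM (adjusted p = 0.00958), and GPR183, a receptor that guides immune cells along oxysterols, from 820.1 ± 140.7 to 4207 ± 449 CPM (adjusted p = 0.0246). NABP1, which encodes a single-stranded DNA binding protein, rose by 3.76 on the log2 scale, the transcription factor CREM by 2.50 and the kinase MAP3K8, which acts below Toll-like receptors, by 2.55 (adjusted p = 0.01, 0.0225 and 0.0225). Each was higher in 4 of 4 donors and also passed with the donor block.

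Among the falls, the transcription factor DACH1 went from 94.78 ± 50.02 to 4.45 ± 3.89 CPM (adjusted p = 0.0434, edgeR) and ZFP36L2, an RNA-binding protein that destabilises transcripts, from 217 ± 22.1 to 31.7 ± 18.0 CPM (adjusted p = 0.0246), both lower in 4 of 4 donors. In the donor-blocked test alone, the myeloid genes OLR1 and THBS1 fell by 5.66 and 3.75 on the log2 scale (adjusted p = 0.00274 and 0.00105 in edgeR, against 0.190 and 0.25 without the block). Their medium levels varied between donors, at 1756 ± 2320 CPM for THBS1.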
